A study of Mus musculus with 11 samples.

How the data were processed

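RNA was sequenced from 11 libraries of mouse P14 CD8 T cells in 3 groups: naive cells from the spleen (3 libraries), reporter-positive cells from tumors (Tcf7-GFP+, 4 libraries) and reporter-negative cells from tumors (Tcf7-GFP-, 4 libraries). Per the labels' protocols, cells were sorted by flow cytometry, RNA was extracted from Trizol lysates, cDNA was made from 5 ng of RNA by template switching (SMART-Seq v4) with 9 cycles of PCR, and 150 pg of cDNA entered Nextera XT library preparation. These kits do not mark the strand of the transcript. Each group was taken from the sample titles, and the donor number in the titles served as the replicate number. The labels number the donors, but do not say that each library comes from a separate animal, so p-values measure the spread between these libraries.

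The deposited values are whole-number read counts per gene, and per the submitters' processing notes the tools were cutadapt 1.3, STAR 2.4.2a and HTSeq 0.6.1 with the mouse build GRCm38; the notes used here give neither their order nor their settings. The annotation release and the strand setting of the counting are not given in the sources used here. The values were used as counts because they are whole, differ in their totals between libraries and carry the 5 summary categories that the counting program writes. The files list 46517 genes by Ensembl identifier. Symbols and coordinates came from the GENCODE M21 annotation of GRCm38 and matched 46005 of them, leaving 512 without a symbol. The 5 categories that name no gene (reads in no gene, ambiguous reads, low-quality, unaligned and multiply aligned reads) held between 39.36% and 48.73% of the reads listed per library and were kept out of library sizes and tests. Reads in no gene made up 16.23% to 19.21% of uniquely aligned reads in naive libraries and 7.28% to 16.85% in tumor libraries.

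Counts assigned to genes ranged from 21800155 to 36017371 per library. Because the libraries were amplified by PCR without molecular identifiers, intervals and floors computed from counts cover counting error only. Replicates were compared before use: chi-square statistics per degree of freedom between libraries of one group were at least 12.9, so no library pair differed by so little as sampling noise. The median within-group SD of log2 CPM over genes was 0.20 in naive, 0.41 in Tcf7-GFP+ and 0.43 in Tcf7-GFP- libraries.

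Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with the 3 groups (17009 genes), library sizes were scaled by TMM, and 1 quasi-likelihood model with a mean per group was fitted to all 11 libraries with robust estimation, so that the groups share an estimate of the spread (common dispersion 0.114). The 3 contrasts were Tcf7-GFP+ against Tcf7-GFP- tumor cells, Tcf7-GFP+ tumor cells against naive cells and Tcf7-GFP- tumor cells against naive cells. P-values were two-sided and adjusted over all tested genes per contrast by Benjamini-Hochberg, with a threshold of 0.05; all adjusted p-values given for genes are from this quasi-likelihood test unless another tool is named. CPM values use TMM-scaled library sizes, and mean log2 CPM of a list uses a prior count of 2.

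A set of 35 gene lists was tested with camera (limma 3.58.1) on the edgeR fit with a preset correlation of 0.01, adjusted over lists per contrast; 33 lists had at least 4 tested members, and the other lists (neutrophil and erythroid markers) were only counted. T cell lists covered naive and central-memory homing and quiescence, memory-like genes, inhibitory receptors, exhaustion-associated, effector-associated and memory-associated transcription factors, cytotoxic effector molecules, NK-type receptors, chemokines, receptors of migration to lymphoid and to inflamed tissue, tissue residency, follicular helper-type genes, costimulatory molecules, cytokine receptors and CD8 T cell identity. Cell state lists covered S-phase, mitosis, glycolysis and hypoxia, oxidative phosphorylation, fatty acid oxidation, cholesterol synthesis, type I interferon and interferon gamma responses, immediate-early and heat-shock genes, apoptosis regulators and the unfolded protein response. Lists for other cell types held markers of B16 melanoma, macrophages and monocytes, dendritic cells, neutrophils, B cells, CD4 and regulatory T cells, fibroblasts and endothelium, and erythroid cells. Tcf7, which defines the sort, was placed in no list. The lists hold 617 different symbols, of which 610 occur in the files. The lists, the comparisons, their tests and the rule for named genes were fixed before the data were examined.

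Named genes were chosen per comparison by rule: a fixed set (Tcf7, Pdcd1, Havcr2, Lag3, Entpd1, Slamf6, Cxcr5, Id3, Il7r, Ccr7, Tox, Gzmb, Ifng and Mki67, and 1 other that is not reported here); the 6 genes with the largest rise and the 6 with the largest fall among those past the threshold with a mean of at least 20 CPM in the higher group, no overlap between replicates and a symbol of a known gene; and from each list up to 3 members that rose, up to 3 that fell and 1 that did not pass. Fold changes against a group without a single count were replaced by a lower bound, with a floor of 3 counts over the whole group. Members of families that share reads (Gzmd to Gzmf, Klra and Klrc receptors, Gbp, Bcl2a1) are given as uncertain, because the counting could split their reads.

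Same-numbered libraries were checked for pairing by correlating their deviations from group means across autosomal genes. Libraries of the 2 tumor groups with the same donor number correlated at 0.245 to 0.294 and each correlated best with its own number. Because every tumor pair exceeded 0.1, the numbers were taken to pair the tumor libraries. Naive and tumor libraries with the same number correlated at -0.179 to 0.0806, and their sex-linked transcripts differed. The main fit, fixed before the data were examined, leaves out these tumor pairs. A fit with donor as a block was listed as an alternative.

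Alternatives were DESeq2 1.42.0, limma-voom with quality weights, RLE and upper-quartile scaling, no low-count filter, a filter of at least 5 CPM in 3 libraries, the donor block, fits of only the 2 compared groups, a 2-fold minimum, camera with an estimated correlation, fry, a prior count of 0.5, V genes with at least 10 counts and leaving out each library in turn. Other alternatives were added after seeing the data: leaving out the 2 Tcf7-GFP+ libraries richest in melanoma transcripts, a melanoma score as covariate, the block in tumor libraries only and a lower distance limit for the position of lists. Comparisons against the shared naive libraries were set beside 20 simulated draws of unchanged groups. Every column of values per sample in the files was used.

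The test was checked on simulated counts drawn with the real means, dispersions and library sizes of 17009 genes, with 200 genes changed. Of genes changed 4-fold, 62.1%, 62.1% and 60.6% were recovered in the 3 contrasts in the order above; of genes changed 2-fold, 26.9%, 29.9% and 19.4%; of genes changed 1.5-fold, 5.97%, 1.49% and 1.49%. Among the 16809 unchanged genes 6, 2 and 0 were called by edgeR, and DESeq2 called 14, 30 and 23. The planted gene list was recovered in each contrast and no other list was called. Genes were drawn independently, without the correlation within real lists, so this does not check the error rate of the list test. All libraries were drawn with 1 dispersion per gene and without pairs. The gene test is thus not checked for the smaller spread of naive libraries (median SD 0.20 against 0.41 and 0.43) or for paired tumor libraries. On the real libraries, other splits of the tumor libraries called up to 21 lists. With 200 genes changed, the depth and 3 or 4 replicates per group thus resolved 4-fold changes in most genes and few changes below 2-fold. The adjusted threshold is less strict where more genes change, so these shares need not hold for the comparisons with naive cells. There 6893 and 6913 genes were called, 4487 and 4556 of them by more than 2-fold.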

Results

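Gene expression was measured by RNA sequencing in mouse P14 cells, CD8 T cells whose transgenic receptor recognizes the viral peptide gp33. The cells also carried a green fluorescent reporter of Tcf7, the gene of the transcription factor Tcf1. Naive reporter-positive P14 cells were sorted from the spleen (3 libraries) or transferred into mice that then received B16 melanoma cells expressing gp33. After vaccination with the peptide and the adjuvant poly(I:C), the transferred cells were sorted from the tumors into reporter-positive (Tcf7-GFP+, 4 libraries) and reporter-negative cells (Tcf7-GFP-, 4 libraries). The total count over genes ranged from 22910689 to 29209050 in naive, from 21800155 to 33657911 in Tcf7-GFP+ and from 30169699 to 36017371 in Tcf7-GFP- libraries. On the first principal component of log2 CPM (53.9% of the variance) the naive libraries lay apart from all 8 tumor libraries.

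Tcf7 (ENSMUSG00000000782, GRCm38 chromosome 11, 52252371 to 52283014), whose reporter defined the sort, was measured first to check the labels. It had 1376 ± 14.9 CPM in naive cells (mean ± SD, n = 3), 621 ± 151 CPM in Tcf7-GFP+ tumor cells (n = 4) and 30.7 ± 13.2 CPM in Tcf7-GFP- tumor cells (n = 4). The lowest Tcf7-GFP+ library had 443 CPM and the highest Tcf7-GFP- library 43.8 CPM, so each library matched its label. Because the sort selected on it, Tcf7 is a check and no independent finding. The transgenic receptor's chains took most V gene counts in each library. Trbv13-3 held between 73.5% (Wilson 95% interval 72.7% to 74.2%, naive replicate 2) and 86.2% (85.5% to 86.9%, Tcf7-GFP- replicate 4) of Trbv counts. Trav14 genes held between 89.7% (89.1% to 90.2%, Tcf7-GFP+ replicate 1) and 94.9% (94.6% to 95.1%, Tcf7-GFP- replicate 3) of Trav counts.

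The comparison of the 2 tumor populations asked which genes differ between P14 cells that kept the Tcf7 reporter and those that lost it in the same tumors. As lists, memory-like and follicular helper-type genes, which share many members, were higher in Tcf7-GFP+ cells. Cytotoxic molecules, effector-associated transcription factors and receptors of inflamed tissue were lower as lists. Slamf6, a surface receptor used to mark memory-like exhausted cells, had 547 ± 177 CPM in Tcf7-GFP+ and 71.1 ± 16 CPM in Tcf7-GFP- cells (mean ± SD, n = 4 each), 7.69-fold higher. Gzmb, which encodes the cytotoxic protease granzyme B, had 1753 ± 949 and 12990.0 ± 7096 CPM, 7.41-fold lower. Havcr2, which encodes the inhibitory receptor Tim-3, had 54.1 ± 35.2 and 633 ± 147 CPM, 11.7-fold lower. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 459 of 17009 tested genes were higher in Tcf7-GFP+ cells and 606 were lower at an adjusted p under 0.05, and 305 and 388 of them by more than 2-fold. The replicates of the 2 groups did not overlap for 1669 genes (9.81% of those tested, where chance gives 2.86%).

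Of the markers fixed for every comparison, these rose. Slamf6 (ENSMUSG00000015314) lies on chromosome 1, 171917515 to 171953170 (log2 fold change 2.94 ± 0.25 (SE), adjusted p = 2.4e-05). Cxcr5 (ENSMUSG00000047880, chromosome 9, 44511787 to 44561877) guides cells to B cell follicles (log2 fold change 3.98 ± 0.46 (SE), adjusted p = 0.000149). Id3 (ENSMUSG00000007872, chromosome 4, 136143497 to 136145755) inhibits E protein transcription factors (log2 fold change 4.30 ± 0.54 (SE), adjusted p = 0.000288). Ccr7 (ENSMUSG00000037944, chromosome 11, 99144196 to 99155077) directs entry into lymph nodes (log2 fold change 2.79 ± 0.56 (SE), adjusted p = 0.00758).

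**Figure D1:**
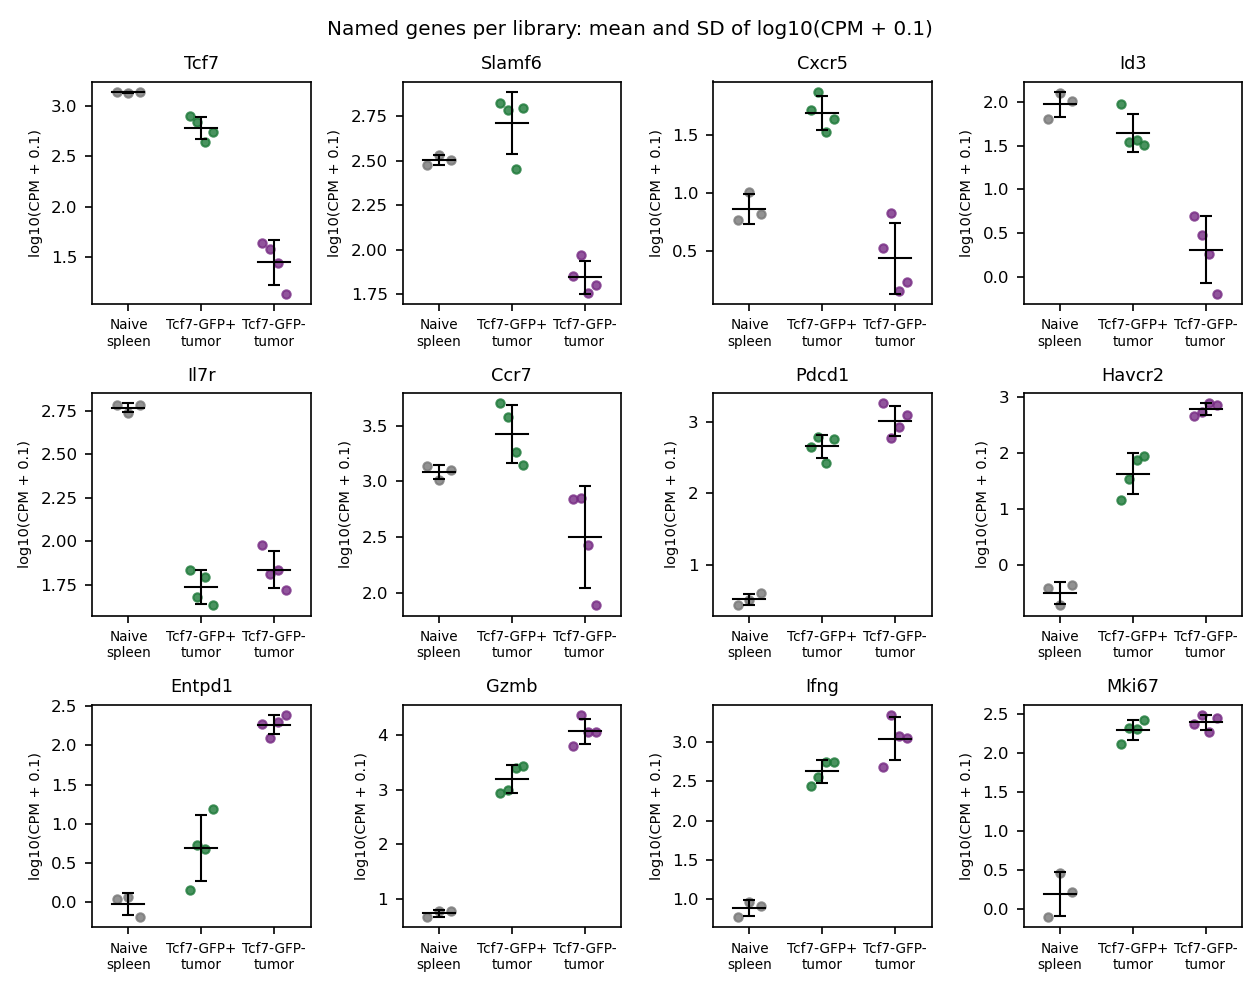
Log10 of CPM plus 0.1 of 12 genes in each library (points) of naive, Tcf7-GFP+ and Tcf7-GFP- cells, with group means (lines) and SD (bars). For Tcf7, Tcf7-GFP+ libraries lie between 443 and 788 CPM and Tcf7-GFP- libraries between 13.6 and 43.8 CPM.

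Others of these markers fell. Havcr2 (ENSMUSG00000020399) lies on chromosome 11, 46454935 to 46481255 (log2 fold change -3.55 ± 0.45 (SE), adjusted p = 0.000274). Entpd1 (ENSMUSG00000048120, chromosome 19, 40612366 to 40741602) encodes the ectonucleotidase CD39 (log2 fold change -4.84 ± 0.54 (SE), adjusted p = 0.000132). Gzmb (ENSMUSG00000015437) lies on chromosome 14, 56258838 to 56262260 (log2 fold change -2.89 ± 0.42 (SE), adjusted p = 0.000692). Il7r, the interleukin 7 receptor, did not pass (log2 fold change -0.34, adjusted p = 0.354). Tox, a factor of exhausted cells (-0.51, adjusted p = 0.481), and Mki67, a proliferation marker (-0.32, adjusted p = 0.6), did not pass either. By size of change, Dapl1 was 23.8-fold higher (adjusted p = 8.83e-06), Nsg2 20.5-fold higher (adjusted p = 1.22e-07) and Tdrp 12.5-fold higher (adjusted p = 0.000729). The chemokine receptor Ccr2 was 32.8-fold lower (adjusted p = 5.62e-05) and the signaling protein Chn2 32.6-fold lower (adjusted p = 5.79e-05). Cd244a, a receptor of NK and T cells, was 31.1-fold lower (adjusted p = 0.000108) and the adhesion receptor Adgrg1 28.6-fold lower (adjusted p = 0.00185). The size of the Adgrg1 fold depends on Tcf7-GFP+ replicate 3, at 5.99 CPM against 0.577 to 1.38 CPM in the others.

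Pdcd1, which encodes PD-1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553), was 2.36-fold lower in Tcf7-GFP+ cells (log2 fold change -1.24 ± 0.32 (SE), adjusted p = 0.0301). This call was lost without Tcf7-GFP+ replicate 1 (adjusted p = 0.0835) or 3 (0.0727) and without Tcf7-GFP- replicate 1 (0.106) or 4 (0.0725), and with the block in tumor libraries only (0.0502). Lag3, another inhibitory receptor, was 1.59-fold lower (adjusted p = 0.0388). Its call was lost without Tcf7-GFP+ replicate 1 (0.0718), 2 (0.0503), 3 (0.0887) or 4 (0.0609). It was also lost without Tcf7-GFP- replicate 1 (0.0804), 3 (0.132) or 4 (0.0799), with the replicate block (0.060) and with the block in tumor libraries only (0.110). The effector cytokine Ifng was 2.86-fold lower (adjusted p = 0.0213), a call lost without Tcf7-GFP+ replicate 1 (0.0713) or 2 (0.0696).

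Of the memory-like genes of chronically stimulated CD8 T cells, 16 of 27 rose and the others did not pass (19 higher and 1 lower adjusted over the list alone). The memory-like median log2 fold change was 1.84 (camera adjusted p = 2.13e-28, adjusted p = 0.0194 with an estimated correlation). Xcl1, a chemokine that attracts dendritic cells, was 3.95-fold higher (adjusted p = 0.0029). Tnfsf8, the ligand of CD30, was 13.9-fold higher (adjusted p = 5.79e-05). In the naive and central-memory homing and quiescence list, 8 of 20 rose and the others did not pass (11 higher and 1 lower adjusted over the list alone). The homing median log2 fold change was 0.57 (camera adjusted p = 1.19e-10, adjusted p = 0.0534 with an estimated correlation). Among memory-associated transcription factors, 6 of 14 rose and the others did not pass (10 higher adjusted over the list alone). The memory factor median log2 fold change was 0.76 (camera adjusted p = 1.09e-09, adjusted p = 0.085 with an estimated correlation). Bach2, a repressor of effector differentiation, was 4.84-fold higher (adjusted p = 0.000145) and Pou6f1 3.74-fold higher (adjusted p = 0.000425). Of follicular helper-type genes, 9 of 15 rose, 1 fell and the others did not pass (10 higher and 2 lower adjusted over the list alone). Many of them, such as Slamf6, Cxcr5, Id3, Tnfsf8 and Il6ra, are also in the memory-like list, so these lists are not separate results. The follicular median log2 fold change was 1.37 (camera adjusted p = 4.44e-13, adjusted p = 0.0194 with an estimated correlation). The interleukin 6 receptor gene Il6ra was 2.94-fold higher (adjusted p = 0.00104) and the transcription factor gene Maf 3.79-fold lower (adjusted p = 0.00111). Of receptors of migration to lymphoid tissue, 4 of 8 rose and the others did not pass (6 higher adjusted over the list alone). The lymphoid migration median log2 fold change was 1.01 (camera adjusted p = 1.52e-08, adjusted p = 0.0534 with an estimated correlation).

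Of cytotoxic effector molecules, 15 of 23 fell and the others did not pass (2 higher and 19 lower adjusted over the list alone). The cytotoxic median log2 fold change was -1.51 (camera adjusted p = 4.05e-27, adjusted p = 0.00486 with an estimated correlation). Gzma, another granzyme, was 24.2-fold lower (adjusted p = 4.92e-05). Gzmf (58.6-fold lower) and Gzme (30.6-fold lower) share reads with their paralogs and are uncertain. Of inhibitory receptors, 2 of 15 rose, 7 fell and the others did not pass (2 higher and 10 lower adjusted over the list alone). The inhibitory receptor median log2 fold change was -0.89 (camera adjusted p = 1.36e-07, adjusted p = 0.0516 with an estimated correlation). Btla, which went the other way, was 2.59-fold higher (adjusted p = 0.00284). Of NK-type receptors, 7 of 16 fell and the others did not pass (9 lower adjusted over the list alone). The NK-type median log2 fold change was -1.49 (camera adjusted p = 3.41e-11, adjusted p = 0.0516 with an estimated correlation). Klrg1, a marker of terminal effector cells, was 47.5-fold lower (adjusted p = 0.000181) and the signaling adaptor Fcer1g 35.5-fold lower (adjusted p = 0.000194). Klra3 (41.1-fold lower) shares reads with other Klra genes and is uncertain. Among effector-associated transcription factors, 5 of 12 fell and the others did not pass (8 lower adjusted over the list alone). The effector factor median log2 fold change was -0.61 (camera adjusted p = 3.16e-10, adjusted p = 0.0194 with an estimated correlation). Prdm1, which encodes Blimp-1, was 13.7-fold lower (adjusted p = 0.000132) and Id2 4.33-fold lower (adjusted p = 4.47e-05). Among exhaustion-associated transcription factors, 4 of 15 fell and the others did not pass (2 higher and 6 lower adjusted over the list alone). The exhaustion factor median log2 fold change was -0.51 (camera adjusted p = 4.76e-05, adjusted p = 0.0499 with an estimated correlation). The Notch pathway factor Rbpj was 1.99-fold lower (adjusted p = 0.000363).

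Of receptors and integrins of migration to inflamed tissue, 6 of 15 fell and the others did not pass (9 lower adjusted over the list alone). The inflamed tissue median log2 fold change was -0.71 (camera adjusted p = 1.82e-17, adjusted p = 0.0194 with an estimated correlation). The integrin gene Itga1 was 19.3-fold lower (adjusted p = 4.92e-05) and the chemokine receptor gene Cxcr6 13.1-fold lower (adjusted p = 8.04e-06). In the tissue residency list, 3 of 23 rose, 10 fell and the others did not pass (3 higher and 13 lower adjusted over the list alone). The residency median log2 fold change was -0.84 (camera adjusted p = 1.12e-09, adjusted p = 0.0194 with an estimated correlation). The ATP-gated channel gene P2rx7 was 5.66-fold higher (adjusted p = 0.000682) and the phosphatase gene Inpp4b 2.25-fold higher (adjusted p = 0.00506). Of cytokine receptors, 3 of 23 rose, 8 fell and the others did not pass (3 higher and 10 lower adjusted over the list alone). The cytokine receptor median log2 fold change was -0.48 (camera adjusted p = 1.84e-05, adjusted p = 0.0681 with an estimated correlation). The interferon receptor chains Ifngr2 and Ifnar2 were 5.97-fold higher (adjusted p = 0.001) and 2.62-fold higher (adjusted p = 0.0001). Il1r2, a decoy receptor of interleukin 1, was 5.84-fold lower (adjusted p = 0.000194) and the growth factor gene Csf1 17.8-fold lower (adjusted p = 0.000692). Of costimulatory molecules, 3 of 18 rose, 3 fell and the others did not pass (4 higher and 6 lower adjusted over the list alone). The costimulatory median log2 fold change was -0.14 (camera adjusted p = 0.632). Their mean log2 fold change of 0.09 had the opposite sign to the median and the test. Tnfsf11, the ligand RANKL, was 6.94-fold higher (adjusted p = 0.003). The costimulatory ligands Cd80 and Cd86 were 5.40-fold lower (adjusted p = 0.00556) and 5.21-fold lower (adjusted p = 0.00313).

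In fatty acid oxidation, 1 of 18 fell and the others did not pass (1 lower adjusted over the list alone). The fatty acid median log2 fold change was 0.10 (camera adjusted p = 0.902). The gene that fell was Acadl, an acyl-CoA dehydrogenase, 1.61-fold lower (adjusted p = 0.0127). Its call was lost when Tcf7-GFP+ replicates 1 and 3 were left out together (adjusted p = 0.140). Of oxidative phosphorylation genes, none of 31 passed edgeR's test (6 at an unadjusted p under 0.05, 0 by DESeq2 and 12 by limma-voom). As a list they were higher (median log2 fold change 0.22, camera adjusted p = 0.00177, adjusted p = 0.574 with an estimated correlation). In the interferon gamma response, 5 of 28 fell and the others did not pass (9 lower adjusted over the list alone). The interferon gamma median log2 fold change was -0.35 (camera adjusted p = 2.18e-06, adjusted p = 0.312 with an estimated correlation). Gbp7 (2.85-fold, adjusted p = 0.000591) and Gbp3 (2.63-fold, adjusted p = 0.000247), which fell, share reads with other Gbp genes and are uncertain.

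Several list results turned on single libraries. Of chemokines, 2 of 9 rose, 4 fell and the others did not pass (2 higher and 5 lower adjusted over the list alone). The chemokine median log2 fold change was -1.49 (camera adjusted p = 0.0243, adjusted p = 0.327 with an estimated correlation). Cxcl10, induced by interferon gamma, was 2.86-fold higher (adjusted p = 0.000712) and Ccl5 20.5-fold lower (adjusted p = 0.000321). The list's call was lost without Tcf7-GFP+ replicate 1 (camera adjusted p = 0.0637) or 2 (0.0502), or Tcf7-GFP- replicate 2 (0.175) or 3 (0.0515). Of S-phase genes, none of 32 passed edgeR's test (0 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom). The S-phase median log2 fold change was -0.04 (camera adjusted p = 0.548). Of mitosis genes, none of 33 passed (0 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom). The mitosis median log2 fold change was -0.04 (camera adjusted p = 0.595). Both lists were called without Tcf7-GFP- replicate 3 (0.0142 and 0.0310), and mitosis also without Tcf7-GFP+ replicate 4 (0.0086), each in the direction of the main test. Without Tcf7-GFP+ replicates 1 and 3 together mitosis was called in the opposite direction (median 0.26, camera adjusted p = 0.0438). In glycolysis and hypoxia, 1 of 25 fell and the others did not pass (1 lower adjusted over the list alone). The glycolysis median log2 fold change was 0.04 (camera adjusted p = 0.37). The test had the opposite sign to the median and to the mean of 0.02, and the list was called without Tcf7-GFP- replicate 3 (0.0470). The gene that fell was the glucose transporter gene Slc2a3, 3.16-fold lower (adjusted p = 0.000363). Of cholesterol synthesis genes, none of 22 passed edgeR's test (4 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom). The cholesterol median log2 fold change was -0.25 (camera adjusted p = 0.0281, adjusted p = 0.574 with an estimated correlation). This call was lost without Tcf7-GFP- replicate 2 (0.414) or 4 (0.0719) or Tcf7-GFP+ replicate 3 (0.102).

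In the type I interferon response, 1 of 34 rose, 1 fell and the others did not pass (2 higher and 3 lower adjusted over the list alone). The interferon median log2 fold change was -0.34 (camera adjusted p = 0.0418, adjusted p = 0.715 with an estimated correlation). Isg20, an antiviral exonuclease, was 2.88-fold lower (adjusted p = 0.0078). The list's call was lost without Tcf7-GFP+ replicate 1 (camera adjusted p = 0.0637), 2 (0.203) or 3 (0.139), or Tcf7-GFP- replicate 3 (0.865) or 4 (0.217). Of immediate-early and heat-shock genes, which tissue dissociation can raise, 2 of 28 fell and the others did not pass (2 lower adjusted over the list alone). The immediate-early median log2 fold change was -0.11 (camera adjusted p = 0.0243, adjusted p = 0.348 with an estimated correlation). The transcription factor gene Egr1 was 2.29-fold lower (adjusted p = 0.00344) and the phosphatase gene Dusp5 2.36-fold lower (adjusted p = 0.000942). Their list lost its call without Tcf7-GFP- replicate 2 (0.114) or Tcf7-GFP+ replicate 3 (0.0631). Of apoptosis regulators, 1 of 21 rose, 2 fell and the others did not pass (1 higher and 5 lower adjusted over the list alone). The apoptosis median log2 fold change was -0.26 (camera adjusted p = 0.0422, adjusted p = 0.107 with an estimated correlation). This ended without Tcf7-GFP+ replicate 1 (0.0612), 3 (0.0631) or 4 (0.0845) or Tcf7-GFP- replicate 1 (0.0600) or 2 (0.101). In the unfolded protein response, 3 of 22 fell and the others did not pass (3 lower adjusted over the list alone). The unfolded protein median log2 fold change was -0.19 (camera adjusted p = 0.0142, adjusted p = 0.52 with an estimated correlation). That call was lost without Tcf7-GFP+ replicate 1 (0.0938) or Tcf7-GFP- replicate 2 (0.471). For CD8 T cell identity, 1 of 16 fell and the others did not pass (2 lower adjusted over the list alone). The CD8 identity median log2 fold change was -0.22 (camera adjusted p = 0.0204, adjusted p = 0.52 with an estimated correlation). It was not called without Tcf7-GFP+ replicate 1 (0.0637) or 3 (0.0631) or Tcf7-GFP- replicate 4 (0.0895).

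Markers of other cell types were compared between the tumor groups. The summed expression of 18 B16 melanoma markers was 570.1 ± 622 CPM in Tcf7-GFP+ cells (mean ± SD, n = 4), 119.9 ± 77.0 CPM in Tcf7-GFP- cells (n = 4) and 36.1 ± 3.76 CPM in naive cells (n = 3). Tcf7-GFP+ replicates 1 and 3 had 622 and 1426 CPM. As a list the melanoma markers were higher in Tcf7-GFP+ cells (median log2 fold change 2.29, camera adjusted p = 0.000125, adjusted p = 0.44 with an estimated correlation), where 1 of 18 rose (1 higher adjusted over the list alone), the ion channel gene Trpm1 (5.68-fold, adjusted p = 0.000309). Naive libraries also held Trpm1 (372 to 496 counts), as did Tcf7-GFP+ replicate 4 (349 counts), the Tcf7-GFP+ library poorest in these markers. Its rise thus did not follow the summed melanoma markers. Without Tcf7-GFP+ replicates 1 and 3 the melanoma list's median was -0.04 (camera adjusted p = 0.84) and the memory-like list's median was 1.41. Without them 244 genes were higher and 283 lower, of which 488 were among the 1065 genes called with all libraries.

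Of macrophage and monocyte markers, 2 of 14 fell and the others did not pass (2 lower adjusted over the list alone). The macrophage median log2 fold change was -0.28 (camera adjusted p = 0.0968). The integrin gene Itgam was 15.9-fold lower (adjusted p = 0.000843). The list was called without Tcf7-GFP+ replicate 3 (camera adjusted p = 0.0465). Of dendritic cell markers, 1 of 10 rose, 1 fell and the others did not pass (4 higher and 1 lower adjusted over the list alone). The dendritic cell median log2 fold change was 0.67 (camera adjusted p = 0.927). Xcr1, the receptor of Xcl1, was 5.03-fold lower (adjusted p = 0.00065). Of B cell markers, 2 of 13 rose and the others did not pass (2 higher adjusted over the list alone). The B cell median log2 fold change was 0.64 (camera adjusted p = 0.0392, adjusted p = 0.112 with an estimated correlation). They were the inhibitory receptor gene Cd22, 7.64-fold higher (adjusted p = 0.00169), and the immunoglobulin heavy chain gene Ighm, 2.60-fold higher (adjusted p = 0.00809). The B cell call was lost without Tcf7-GFP+ replicate 1 (0.0734) or Tcf7-GFP- replicate 2 (0.149). In the fibroblast and endothelium list, 1 of 10 rose and the others did not pass (1 higher adjusted over the list alone). The fibroblast median log2 fold change was 0.73 (camera adjusted p = 0.16). Of CD4 and regulatory T cell markers, none of 6 passed edgeR's test (1 at an unadjusted p under 0.05, 1 by DESeq2 and 1 by limma-voom). Their median log2 fold change was -0.56 (camera adjusted p = 0.193). Of neutrophil markers, 1 of 3 fell (1 lower adjusted over the list alone, median -0.80). The single tested erythroid marker, Hbb-bs, did not pass edgeR's test (1 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom, log2 fold change 4.96). Its fold change rests on Tcf7-GFP+ replicate 3, with 412 counts against 7 to 11 in the others of that group.

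By camera, 8 of 33 lists were higher and 16 lower in Tcf7-GFP+ cells. With an estimated correlation 2 stayed higher (memory-like and follicular helper-type genes) and 5 stayed lower (cytotoxic molecules, effector-associated and exhaustion-associated transcription factors, migration to inflamed tissue and tissue residency). The 2 higher lists share many members and are not separate results. The gene counts depended on single libraries: without Tcf7-GFP- replicate 2 they were 1300.0 higher and 1076 lower, and without Tcf7-GFP- replicate 3 or 4 the higher genes numbered 269 and 298.

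The comparison of Tcf7-GFP+ tumor cells with naive cells asked how cells that kept the reporter differed from the population they started as, where tissue, vaccination and dissociation differ together. In Tcf7-GFP+ tumor cells, cell cycle genes, inhibitory receptors, chemokines and cytotoxic molecules were, as lists, higher than in naive cells and homing genes were lower. Mki67 had 200.4 ± 54.1 CPM in Tcf7-GFP+ tumor cells (mean ± SD, n = 4) and 1.69 ± 1.07 CPM in naive cells (n = 3), 118-fold higher (log2 fold change 6.89 ± 0.44 (SE), adjusted p = 4.94e-08). Pdcd1 had 479 ± 159 and 3.18 ± 0.638 CPM, 151-fold higher (log2 fold change 7.24 ± 0.48 (SE), adjusted p = 5.74e-08). Il7r fell from 586 ± 33.4 to 55.5 ± 12.2 CPM, 10.6-fold lower (log2 fold change -3.40 ± 0.22 (SE), adjusted p = 4.89e-08). In edgeR's quasi-likelihood test 4170 genes were higher and 2723 lower, 2819 and 1668 of them by more than 2-fold. With upper-quartile scaling the counts were 3531 and 3560.0, and the median log2 fold change over all genes was -0.11 in place of 0.07. The replicates did not overlap for 8433 genes (49.6%, where chance gives 5.71%).

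Havcr2 was 223-fold higher (adjusted p = 9.34e-07), Lag3 376-fold higher (adjusted p = 2.41e-10) and Entpd1 7.35-fold higher (adjusted p = 0.00179) in Tcf7-GFP+ tumor cells than in naive cells. Gzmb was 317-fold higher (adjusted p = 1.59e-07), Ifng 57.5-fold higher (adjusted p = 6.17e-07) and Cxcr5 6.85-fold higher (adjusted p = 0.000361). Tcf7 was 2.22-fold lower (log2 fold change -1.15 ± 0.30 (SE), adjusted p = 0.00653). Tox did not pass (log2 fold change 0.47, adjusted p = 0.38). Ccr7 did not pass (adjusted p = 0.0947) but did with the replicate block (0.00472), although naive and tumor libraries were not found to pair by number. Id3 (-0.98, adjusted p = 0.135) passed without Tcf7-GFP+ replicate 1 (0.0252) and not with all libraries. Slamf6 was 1.71-fold higher (adjusted p = 0.0247). Its call was lost without naive replicate 1 (0.172), 2 (0.119) or 3 (0.0915) or Tcf7-GFP+ replicate 1 (0.0685), 2 (0.0585) or 4 (0.0756). By size of change, Pbk, a mitotic kinase without a count in naive cells, was at least 1140.0-fold higher against a floor of 3 counts over the naive group. The gut-homing receptor gene Ccr9 was 241-fold lower (adjusted p = 5.5e-09) and the transporter gene Slc16a5 144-fold lower (adjusted p = 1.91e-10). Itgae, whose integrin binds epithelial cadherin, was 114-fold lower (adjusted p = 1.62e-09), and Dntt, the terminal transferase of receptor rearrangement, 103-fold lower (adjusted p = 1.58e-06).

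Of mitosis genes all 33 rose (33 higher adjusted over the list alone). The mitosis median log2 fold change was 5.89 (camera adjusted p = 1.28e-48, adjusted p = 0.0495 with an estimated correlation). Ccna2, a cyclin gene, was 381-fold higher (adjusted p = 7.76e-09). Of S-phase genes, 31 of 32 rose and the other did not pass (32 higher adjusted over the list alone). The S-phase median log2 fold change was 3.13 (camera adjusted p = 1.19e-35, adjusted p = 0.0495 with an estimated correlation). The replication licensing factor Cdc6 was 129-fold higher (adjusted p = 6.01e-08) and the ribonucleotide reductase subunit Rrm2 57.7-fold higher (adjusted p = 4.72e-08). Of glycolysis and hypoxia genes, 22 of 25 rose, 1 fell and the others did not pass (23 higher and 1 lower adjusted over the list alone). The glycolysis median log2 fold change was 2.19 (camera adjusted p = 7.13e-19, adjusted p = 0.0495 with an estimated correlation). The lactate transporter gene Slc16a3 was 94.9-fold higher (adjusted p = 1.15e-07) and the hexokinase gene Hk2 41.2-fold higher (adjusted p = 4.74e-07). Of oxidative phosphorylation genes, 28 of 31 rose and the others did not pass (28 higher adjusted over the list alone). The oxidative median log2 fold change was 1.16 (camera adjusted p = 2.1e-11, adjusted p = 0.308 with an estimated correlation). Cox7a2, a cytochrome c oxidase subunit, was 3.80-fold higher (adjusted p = 1.19e-06). In the unfolded protein response, 16 of 22 rose, 1 fell and the others did not pass (16 higher and 1 lower adjusted over the list alone). The unfolded protein median log2 fold change was 1.33 (camera adjusted p = 4.71e-05, adjusted p = 0.308 with an estimated correlation). Asparagine synthetase (Asns) was 328-fold higher (adjusted p = 1.85e-06), a fold that rests on 15, 2 and 2 counts in naive replicates 1, 2 and 3. Of apoptosis regulators, 7 of 21 rose, 5 fell and the others did not pass (8 higher and 5 lower adjusted over the list alone). The apoptosis median log2 fold change was 0.35 (camera adjusted p = 0.0111, adjusted p = 0.0495 with an estimated correlation). The survival gene Bcl2 was 3.01-fold lower (adjusted p = 1.76e-05).

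Of homing and quiescence genes, 13 of 20 fell and the others did not pass (15 lower adjusted over the list alone). The homing median log2 fold change was -2.26 (camera adjusted p = 2.91e-11, adjusted p = 0.0495 with an estimated correlation). Lef1 and Klf2, transcription factors that maintain naive T cells, were 8.27-fold lower (adjusted p = 5.51e-08) and 8.71-fold lower (adjusted p = 8.69e-08). Of memory-like genes, 12 of 27 rose, 9 fell and the others did not pass (16 higher and 9 lower adjusted over the list alone). The memory-like median log2 fold change was 0.85 (camera adjusted p = 0.588). Xcl1 was 552-fold higher (adjusted p = 3.47e-08), the costimulatory receptor Tnfrsf4 94.5-fold higher (adjusted p = 7.02e-09) and Il6ra 39.1-fold lower (adjusted p = 4.57e-09). Of inhibitory receptors, 7 of 15 rose, 2 fell and the others did not pass (7 higher and 2 lower adjusted over the list alone). The inhibitory receptor median log2 fold change was 0.83 (camera adjusted p = 4.01e-07, adjusted p = 0.0495 with an estimated correlation). Of exhaustion-associated transcription factors, 10 of 15 rose, 1 fell and the others did not pass (10 higher and 1 lower adjusted over the list alone). The exhaustion factor median log2 fold change was 1.64 (camera adjusted p = 3.65e-08, adjusted p = 0.0441 with an estimated correlation). Of effector-associated ones, 9 of 12 rose, 1 fell and the others did not pass (9 higher and 1 lower adjusted over the list alone). The effector factor median log2 fold change was 2.29 (camera adjusted p = 8.26e-08, adjusted p = 0.0441 with an estimated correlation). Bhlhe40, a member of both lists, was 159-fold higher (adjusted p = 6.16e-10) and Tbx21, which encodes T-bet, 14.2-fold higher (adjusted p = 6.16e-08). Of cytotoxic molecules, 15 of 23 rose, 1 fell and the others did not pass (15 higher and 1 lower adjusted over the list alone). The cytotoxic median log2 fold change was 1.82 (camera adjusted p = 2.8e-09, adjusted p = 0.0495 with an estimated correlation). The granzyme gene Gzmk was 108-fold higher (adjusted p = 6.17e-08). Of chemokines, 8 of 9 rose and the other did not pass (8 higher adjusted over the list alone). The chemokine median log2 fold change was 5.62 (camera adjusted p = 3.06e-08, adjusted p = 0.0495 with an estimated correlation). Of costimulatory molecules, 12 of 18 rose, 2 fell and the others did not pass (12 higher and 2 lower adjusted over the list alone). The costimulatory median log2 fold change was 2.49 (camera adjusted p = 1.83e-09, adjusted p = 0.0441 with an estimated correlation). The receptor gene Tnfrsf9 was 113-fold higher (adjusted p = 8.66e-10) and Cd40lg 24.3-fold lower (adjusted p = 8.41e-05). The size of the Cd40lg fold depends on Tcf7-GFP+ replicate 4, with 75 counts against 13 to 20 in the others.

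Of melanoma markers, 15 of 18 rose, 1 fell and the others did not pass (16 higher and 1 lower adjusted over the list alone). The melanoma median log2 fold change was 4.70 (camera adjusted p = 0.0364, adjusted p = 0.664 with an estimated correlation). This call was lost without Tcf7-GFP+ replicate 1 (0.0916) or 3 (0.0728). Of dendritic cell markers, 6 of 10 rose and the others did not pass (6 higher adjusted over the list alone). The dendritic cell median log2 fold change was 2.64 (camera adjusted p = 0.0201, adjusted p = 0.351 with an estimated correlation). Their call was lost without Tcf7-GFP+ replicate 1 (0.0512). The integrin gene Itgax was 95.5-fold higher (adjusted p = 4.68e-06), a fold that rests on 11, 5 and 32 counts in naive replicates 1, 2 and 3. In the tissue residency list, 11 of 23 rose, 4 fell and the others did not pass (12 higher and 5 lower adjusted over the list alone). The residency median log2 fold change was 0.55 (camera adjusted p = 0.0426, adjusted p = 0.308 with an estimated correlation). That call was lost without naive replicate 1 (0.0547) or Tcf7-GFP+ replicate 1 (0.0876). In the type I interferon response, 5 of 34 rose, 11 fell and the others did not pass (5 higher and 11 lower adjusted over the list alone). The interferon median log2 fold change was -0.25 (camera adjusted p = 0.0642). The list was called lower with the replicate block (median -0.44, adjusted p = 0.00973) and without naive replicate 1 (0.0486) or 2 (0.0437) or Tcf7-GFP+ replicate 4 (0.0179). The block ties naive to tumor libraries by number, a pairing that was not found. Oas2 and Oasl2, antiviral genes induced by interferon, were 13.95-fold lower (adjusted p = 0.00018) and 8.12-fold lower (adjusted p = 2.51e-05). Of immediate-early and heat-shock genes, 9 of 28 rose, 9 fell and the others did not pass (9 higher and 10 lower adjusted over the list alone). The immediate-early median log2 fold change was -0.31 (camera adjusted p = 0.146). They were called lower without naive replicate 1 (0.0309), and without it 4 lists in place of 2 were called lower. The transcription factor genes Fos and Jun were 10.8-fold lower (adjusted p = 3.59e-05) and 5.04-fold lower (adjusted p = 8.9e-06), and Atf3 23.1-fold higher (adjusted p = 1.02e-06).

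By camera 17 lists were higher and 2 lower than in naive cells, and 10 and 1 with an estimated correlation. For CD4 and regulatory T cell markers the median log2 fold change (0.56) had the opposite sign to the mean (-0.14) and the test, and for fibroblast and endothelium markers the median (0.72) and mean (1.11) had the opposite sign to the test (camera adjusted p = 0.908 and 0.798).

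The comparison of Tcf7-GFP- tumor cells with naive cells asked the same of the cells that lost the reporter. Gzmb rose from 5.53 ± 0.796 CPM in naive cells (mean ± SD, n = 3) to 12990.0 ± 7096 CPM in Tcf7-GFP- tumor cells (n = 4), 2349-fold higher (log2 fold change 11.20 ± 0.69 (SE), adjusted p = 2.23e-08). Havcr2 rose from 0.244 ± 0.135 to 633 ± 147 CPM, 2607-fold higher (log2 fold change 11.35 ± 0.77 (SE), adjusted p = 4.77e-08). The size of this fold rests on 10, 3 and 9 counts in naive replicates 1, 2 and 3. The receptor Slamf6 was 4.49-fold lower (adjusted p = 9.45e-06) and Id3 38.8-fold lower (adjusted p = 4.96e-06). In edgeR's quasi-likelihood test 4086 genes were higher and 2827 lower, 2672 and 1884 of them by more than 2-fold. With upper-quartile scaling the counts were 3305 and 3730.0, and the median log2 fold change over all genes was -0.24 in place of -0.04. The replicates did not overlap for 8557 genes (50.3%, where chance gives 5.71%).

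Pdcd1 was 358-fold higher (adjusted p = 1.61e-08), Lag3 597-fold higher (adjusted p = 8.66e-11) and Entpd1 209.9-fold higher (adjusted p = 1.12e-06) in Tcf7-GFP- tumor cells than in naive cells. Ifng was 164-fold higher (adjusted p = 9.63e-08) and Mki67 147-fold higher (adjusted p = 2.4e-08). Tcf7 was 44.8-fold lower (adjusted p = 2.51e-08) and Il7r 8.32-fold lower (adjusted p = 7.25e-08). Cxcr5 was 2.30-fold lower (adjusted p = 0.0447), a call lost without naive replicate 2 (0.136) or 3 (0.0675) or Tcf7-GFP- replicate 1 (0.0749), 3 (0.102) or 4 (0.0984). Ccr7 was 2.81-fold lower (adjusted p = 0.0477), a call lost without naive replicate 1 (0.0951), 2 (0.0597) or 3 (0.107) or Tcf7-GFP- replicate 3 (0.113) or 4 (0.0534). Tox (log2 fold change 0.99, adjusted p = 0.0632) passed without Tcf7-GFP- replicate 2 (0.00697) or 3 (0.0488) and not with all libraries. By size of change, Pbk was at least 851-fold higher against a floor of 3 counts over the naive group. Lgals3, a galectin gene, was 1281-fold higher (adjusted p = 5.58e-09), Ccr9 367-fold lower (adjusted p = 2.22e-09) and Slc16a5 328-fold lower (adjusted p = 5.83e-11).

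Of cytotoxic molecules, 19 of 23 rose and the others did not pass (21 higher adjusted over the list alone). The cytotoxic median log2 fold change was 4.18 (camera adjusted p = 3.05e-19, adjusted p = 0.011 with an estimated correlation). Of NK-type receptors, 10 of 16 rose and the others did not pass (11 higher and 1 lower adjusted over the list alone). The NK-type median log2 fold change was 4.46 (camera adjusted p = 4.13e-09, adjusted p = 0.063 with an estimated correlation). The activating receptor gene Klrk1 was 207-fold higher (adjusted p = 1.9e-09). Of effector-associated transcription factors, 10 of 12 rose and the others did not pass (10 higher adjusted over the list alone). The effector factor median log2 fold change was 2.96 (camera adjusted p = 3.92e-13, adjusted p = 0.011 with an estimated correlation). Of exhaustion-associated ones, 11 of 15 rose and the others did not pass (12 higher adjusted over the list alone). The exhaustion factor median log2 fold change was 2.45 (camera adjusted p = 4e-11, adjusted p = 0.011 with an estimated correlation). Prdm1, a member of both lists, was 60.8-fold higher (adjusted p = 7.7e-07). Of inhibitory receptors, 9 of 15 rose, 3 fell and the others did not pass (9 higher and 3 lower adjusted over the list alone). The inhibitory receptor median log2 fold change was 2.32 (camera adjusted p = 5.32e-10, adjusted p = 0.0311 with an estimated correlation). Of receptors of migration to inflamed tissue, 11 of 15 rose, 2 fell and the others did not pass (11 higher and 2 lower adjusted over the list alone). The inflamed tissue median log2 fold change was 3.55 (camera adjusted p = 3.04e-07, adjusted p = 0.0678 with an estimated correlation). The chemokine receptor genes Cx3cr1 and Ccr2 were 807-fold higher (adjusted p = 7.7e-07) and 191-fold higher (adjusted p = 3.74e-07). The size of the Cx3cr1 fold rests on 2, 0 and 2 counts in naive replicates 1, 2 and 3. Of chemokines, 7 of 9 rose and the others did not pass (7 higher adjusted over the list alone). The chemokine median log2 fold change was 7.12 (camera adjusted p = 5.51e-09, adjusted p = 0.032 with an estimated correlation). Ccl3 and Ccl4 were 502-fold higher (adjusted p = 3.29e-07) and 289-fold higher (adjusted p = 1.58e-07). In the tissue residency list, 14 of 23 rose, 5 fell and the others did not pass (17 higher and 5 lower adjusted over the list alone). The residency median log2 fold change was 1.42 (camera adjusted p = 3.31e-05, adjusted p = 0.0458 with an estimated correlation). Its member Itgae was 78.1-fold lower (adjusted p = 1.92e-09).

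Of homing and quiescence genes, 16 of 20 fell and the others did not pass (16 lower adjusted over the list alone). The homing median log2 fold change was -2.89 (camera adjusted p = 3.23e-18, adjusted p = 0.0259 with an estimated correlation). Klf2 was 18.6-fold lower (adjusted p = 6.39e-09). Of receptors of migration to lymphoid tissue all 8 fell (8 lower adjusted over the list alone). The lymphoid migration median log2 fold change was -1.41 (camera adjusted p = 1.91e-07, adjusted p = 0.0617 with an estimated correlation). S1pr1, which lets cells leave lymphoid tissue, was 14.9-fold lower (adjusted p = 2.62e-05). Of memory-like genes, 10 of 27 rose, 15 fell and the others did not pass (10 higher and 15 lower adjusted over the list alone). The memory-like median log2 fold change was -1.10 (camera adjusted p = 0.000303, adjusted p = 0.285 with an estimated correlation). Of memory-associated transcription factors, 3 of 14 rose, 8 fell and the others did not pass (3 higher and 8 lower adjusted over the list alone). The memory factor median log2 fold change was -1.09 (camera adjusted p = 6.11e-05, adjusted p = 0.221 with an estimated correlation). Of mitosis genes all 33 rose (33 higher adjusted over the list alone). The mitosis median log2 fold change was 5.84 (camera adjusted p = 1.29e-44, adjusted p = 0.0458 with an estimated correlation). Of S-phase genes, 31 of 32 rose and the other did not pass (31 higher adjusted over the list alone). The S-phase median log2 fold change was 3.21 (camera adjusted p = 4.19e-33, adjusted p = 0.0617 with an estimated correlation). Of glycolysis and hypoxia genes, 23 of 25 rose and 2 fell (23 higher and 2 lower adjusted over the list alone). The glycolysis median log2 fold change was 2.30 (camera adjusted p = 1.56e-18, adjusted p = 0.0458 with an estimated correlation). In the interferon gamma response, 13 of 28 rose and the others did not pass (15 higher and 1 lower adjusted over the list alone). The interferon gamma median log2 fold change was 0.58 (camera adjusted p = 0.000753, adjusted p = 0.416 with an estimated correlation). The transcription factor gene Irf8 was 117-fold higher (adjusted p = 5.41e-11). Of melanoma markers, 7 of 18 rose, 2 fell and the others did not pass (8 higher and 2 lower adjusted over the list alone). The melanoma median log2 fold change was 2.70 (camera adjusted p = 0.348). Of cholesterol synthesis genes, 13 of 22 rose, 1 fell and the others did not pass (13 higher and 1 lower adjusted over the list alone). The cholesterol median log2 fold change was 0.85 (camera adjusted p = 0.018, adjusted p = 0.533 with an estimated correlation). This call was lost without Tcf7-GFP- replicate 2 (0.0615). Of follicular helper-type genes, 5 of 15 rose, 7 fell and the others did not pass (6 higher and 8 lower adjusted over the list alone). The follicular median log2 fold change was -0.91 (camera adjusted p = 0.0878). They were called lower without naive replicate 1 (0.0451).

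Camera called 19 lists higher and 4 lower than in naive cells, and 10 and 1 with an estimated correlation. For fibroblast and endothelium markers the median (0.21) and mean (0.18) had the opposite sign to the test (camera adjusted p = 0.452).

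Most genes that differed from naive cells in one tumor population did so in the other. Both comparisons with naive cells called 3335 genes higher and 2050 lower, where independent lists of these sizes would share 1002 and 453, and 14 genes went in opposite directions. Across genes, which are not independent replicates, the log2 fold changes correlated at 0.885 with a covariance of 2.39. Unchanged groups simulated against the shared naive libraries (20 draws) gave a median correlation of 0.396 and covariance of 0.106, and in the data the covariance exceeded the simulated one by 2.28. The same sign was seen for 83.7% of genes and in 60.1% of simulated ones. The drawn naive libraries carried their error into both comparisons, so the simulated covariance (highest draw 0.116) is an estimate of what shared controls add. The 3 naive libraries cannot be split so that each part keeps 2, so the excess was not checked with separate controls.

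Of the 459 genes higher in Tcf7-GFP+ than in Tcf7-GFP- tumor cells, 137 were lower than in naive cells in both populations, 128 were lower in Tcf7-GFP- cells alone, 93 were higher in Tcf7-GFP+ cells alone and 62 were higher in both. Of the 606 lower genes, 272 were higher than in naive cells in both populations, 174 were higher in Tcf7-GFP- cells alone and 101 were lower in Tcf7-GFP+ cells alone. These classes rest on which tests passed, and a call in a single population is not a tested difference.

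Gene lists placed Tcf7-GFP+ cells between naive and Tcf7-GFP- cells in most cases. Over 18 lists of T cell genes and cell states, without those of other cell types and CD8 identity, whose means differed by more than 1 log2 unit between naive and Tcf7-GFP- cells, Tcf7-GFP+ cells had covered a median of 67.1% of that distance, and single Tcf7-GFP+ libraries covered 62.8% to 72.8%. The lists ranged from memory-associated transcription factors at 15.2% (4.13% to 24.8% when a library was left out) to costimulatory molecules at 105.7% (100.4% to 109.8%). Mitosis genes were at 99.5%, effector-associated transcription factors at 69.3%, inhibitory receptors at 65.0% and cytotoxic molecules at 56.0%. Memory-like genes lay outside the range, with a mean log2 CPM of 5.80 ± 0.02 in naive (SD, n = 3), 6.93 ± 0.31 in Tcf7-GFP+ (n = 4) and 5.20 ± 0.48 in Tcf7-GFP- cells (n = 4). Follicular helper-type genes, many of which are also in the memory-like list, did too, at 4.07 ± 0.16, 5.21 ± 0.27 and 3.71 ± 0.38. These are means over members that went both ways against naive cells. At an unadjusted p under 0.05 in edgeR's test, 16 of 27 memory-like genes were higher and 9 lower in Tcf7-GFP+ cells. Of 15 follicular helper-type genes, 10 were higher and 3 lower. For list means the exact permutation test of the 2 tumor groups (4 against 4, two-sided, without regard to pairs) can give no p below 0.0286. None passed 0.05 after Benjamini-Hochberg adjustment over lists (lowest 0.0673).

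**Figure D2:**
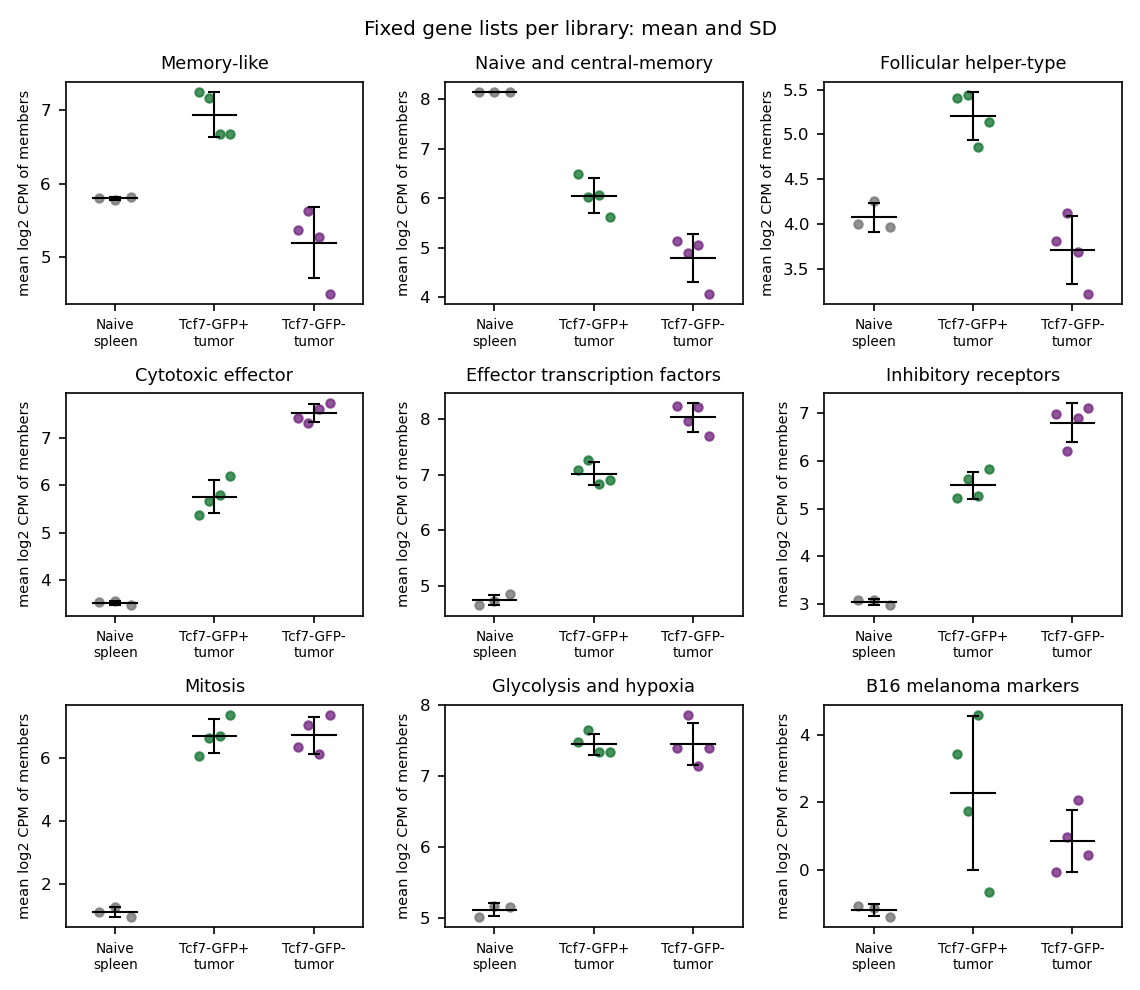
Mean log2 CPM (prior count 2) of the members of 9 gene lists in each library (points), with group means (lines) and SD (bars). The means of memory-like and follicular helper-type genes, lists that share many members, were highest in Tcf7-GFP+ cells, although single members went both ways against naive cells. Mitosis genes were at 6.69 in Tcf7-GFP+ and 6.72 in Tcf7-GFP- cells.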

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

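No test of an explanation was run for the values in this part. In 158 tests of single libraries against the others of their group, with groups of 4, the gap to the nearest library exceeded Dixon's critical share of the range in 6 cases, and chance alone gives about 1 in 20.

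Slamf6 in Tcf7-GFP+ replicate 3 was at 285 CPM, below the other libraries of its group (608 to 671 CPM). Id3 in Tcf7-GFP+ replicate 1 was at 94.1 CPM, above the others (32.5 to 36.5 CPM). Klra3, which shares reads with other Klra genes, was at 1.40 CPM in Tcf7-GFP+ replicate 4 and at 0.428 to 0.474 CPM in the others. Adgrg1 was at 5.99 CPM in Tcf7-GFP+ replicate 3 and at 0.577 to 1.38 CPM in the others. The mean log2 CPM of NK-type receptors was 2.46 in Tcf7-GFP- replicate 2 and 4.03 to 4.13 in the others of its group. Oxidative phosphorylation genes had a mean log2 CPM of 7.81 in Tcf7-GFP+ replicate 1 and 8.09 to 8.12 in the others.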

How the results depend on the processing

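Leaving out Tcf7-GFP+ replicates 1 and 3 together, the melanoma covariate, the block in tumor libraries only and the smaller distance limit for list positions were chosen after seeing the data. Between the tumor populations, the main counts of 459 higher and 606 lower genes became 709 and 1145 with DESeq2, and 1433 and 1111 with limma-voom. Without a low-count filter they were 792 and 986. With only the 2 compared groups in the fit the higher genes numbered 253, and with more than 2-fold 305 were higher and 388 lower. Leaving out a single library gave 269 to 1300.0 higher and 415 to 1076 lower genes, the highest without Tcf7-GFP- replicate 2 and the lowest without Tcf7-GFP- replicate 3. Without Tcf7-GFP+ replicates 1 and 3 they were 244 and 283, and with a melanoma score as covariate 208 and 340.0. The limit of 2-fold drops genes by construction, and for the other settings the cause was not tested.

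Against naive cells, requiring more than 2-fold left 1668 lower genes in Tcf7-GFP+ cells, 2672 higher and 1884 lower genes in Tcf7-GFP- cells, and an overlap of 2149 higher and 1244 lower genes. Among lists, an estimated correlation left 2 higher and 5 lower between the tumor populations, and 10 higher and 1 lower in each comparison with naive cells. Between the tumor populations fry called 9 lists lower, as did the filter of at least 5 CPM in 3 libraries. In Tcf7-GFP+ against naive cells, lists called lower ranged from 2 to 4 when a single library was left out. Without Tcf7-GFP+ replicates 1 and 3 the mitosis list's median log2 fold change between the tumor populations turned from -0.04 to 0.26 (camera adjusted p = 0.0438), and that of melanoma markers from 2.29 to -0.0396 (0.84); the cause was not tested. This setting also ended the list calls of cholesterol synthesis (0.225), the type I interferon response (0.226), apoptosis regulators (0.106), the unfolded protein response (0.0552), B cell markers (0.144) and CD8 T cell identity (0.341), and made that of macrophage and monocyte markers (0.0144). The position of Tcf7-GFP+ cells between the other groups ranged from 65.2% to 69.1% when a library was left out.

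With the donor number as a replicate block, the counts between the tumor populations were 646 higher and 742 lower, and 1028 of the 1065 genes called without it kept their call. Against naive cells they were 4179 and 2887 in Tcf7-GFP+ and 4045 and 2961 in Tcf7-GFP- cells, with 3351 higher and 2213 lower in both. Lists called with the block numbered 8 higher and 16 lower, 17 and 3, and 19 and 4 in the 3 comparisons. Tcf7 had a log2 fold change of 4.42 between the tumor populations and of -5.42 in Tcf7-GFP- against naive cells with the block. Of results in the report, the block ended the call of Lag3 (0.060) and made those of Ccr7 (0.00472) and the type I interferon list (0.00973) in Tcf7-GFP+ against naive cells, and it changed no other call named there. Naive and tumor libraries were not found to pair by number, so block results against naive cells rest on a pairing that was not shown. The block in tumor libraries only gave 480.0 higher and 617 lower genes between the tumor populations and kept 864 of the 1065 calls. Of genes named by rule it ended 6 calls, among them Pdcd1 (0.0502) and Lag3 (0.110), and made 1.

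For genes named by rule, alternatives kept direction and side of the threshold 1390.0, 1667 and 1679 times in the 3 comparisons, ended a call 87, 55 and 50 times, made a call 24, 25 and 16 times, and reversed none. For lists they kept it 387, 365 and 374 times, ended a call 65, 19 and 14 times, made one 6, 10 and 6 times, and reversed 2, 0 and 0. At this depth and number of replicates, 26.9%, 29.9% and 19.4% of simulated 2-fold changes were recovered, so a gene that did not pass is not shown to be unchanged.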

Other observations

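The tests on melanoma transcripts, memory-like genes, sex-linked transcripts and Ighm were chosen only after their results were seen, except the autosomal correlations. In Tcf7-GFP- against naive cells, lists called but not described in the report were all higher: those of apoptosis regulators (9 of 21 rose and 3 fell, camera adjusted p = 0.00147, adjusted p = 0.0311 with an estimated correlation), the unfolded protein response (16 of 22 rose and 1 fell, camera adjusted p = 7.74e-07, adjusted p = 0.199 with an estimated correlation) and costimulatory molecules (14 of 18 rose and 3 fell, camera adjusted p = 9.12e-09, adjusted p = 0.0259 with an estimated correlation). The others were oxidative phosphorylation (26 of 31 rose, camera adjusted p = 3.04e-07, adjusted p = 0.362 with an estimated correlation), cytokine receptors (12 of 23 rose and 8 fell, 0.00686 and 0.200) and dendritic cell markers (6 of 10 rose, 0.0178 and 0.290). In Tcf7-GFP+ against naive cells, NK-type receptors (5 of 16 rose and 1 fell, camera adjusted p = 0.000288, adjusted p = 0.285 with an estimated correlation) and receptors of migration to inflamed tissue (9 of 15 rose and 2 fell, 0.0114 and 0.351) were higher as lists, and receptors of migration to lymphoid tissue lower (4 of 8 fell and 1 rose, 0.00287 and 0.308). In Tcf7-GFP- against naive cells the survival gene Bcl2 was 4.04-fold lower (adjusted p = 1.53e-06).

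Counted over all splits, the gene counts in each comparison with naive cells met the bound set beforehand, a share under 0.05 of splits with as many genes. The share of 1 of 35 is the smallest that these splits can give and is unadjusted over the comparisons, so it does not firmly exclude chance. Between the tumor populations chance cannot be excluded, because the numbers were taken as pairs and too few splits part every pair. Every other split mixes libraries of both groups, so a real difference widens its spread and lowers its count. Among 35 splits of the same libraries the real split alone (1 of 35) gave as many genes, with 665 between the tumor populations (highest other split 0 by edgeR), 7352 in Tcf7-GFP+ against naive (highest other 0) and 7097 in Tcf7-GFP- against naive cells (highest other 2). These counts come from fits of the compared libraries alone. For lists in Tcf7-GFP+ against naive cells the real split alone called as many (1 split, 19 lists, highest other 18). Its share is under the 0.05 set beforehand. A margin of 1 list, unadjusted over the comparisons, does not firmly exclude chance. Nor can chance be excluded for the list counts between the tumor populations (3 splits, 21 lists, highest other 21) or in Tcf7-GFP- against naive cells (2 splits, 23 lists, highest other 25). Of the splits of the tumor libraries, 8 part every same-numbered pair, and the highest of the others among them called 0 genes and 21 lists; with the numbers taken as pairs, these 8 are too few for a share under 0.05.

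Melanoma transcripts were high in some Tcf7-GFP+ libraries, led by Dct (367 CPM), Pmel (360.2 CPM), Tyrp1 (287 CPM) and Gpnmb (147 CPM) in replicate 3, although the sort selected CD8 and a congenic marker. Of 18 markers, 4 reach 1 CPM in naive cells. Melanoma cells or their RNA in the sorted material may be the source: 88.89% of the markers were over 4-fold higher in the Tcf7-GFP+ library richest than in that poorest in the other markers, with a median of 61.7-fold. Expression by Tcf7-GFP+ T cells in general cannot be told apart from it: the list mean was 1.42 log2 CPM higher in Tcf7-GFP+ than in Tcf7-GFP- libraries, but the libraries of the 2 groups overlapped. Tcf7-GFP+ replicate 4 had a marker sum of 34.3 CPM, within the naive range of 31.9 to 39.0 CPM, and a single library does not decide it. As the whole cause of the higher memory-like genes this material is argued against, since their median stayed at 1.41 without those libraries.

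Sex-linked transcripts differed between naive and tumor libraries of the same number. Summed Y-linked expression was 3.55, 356 and 204.8 CPM in naive replicates 1, 2 and 3, 349 and 372 CPM in the tumor libraries of donor 1, and at most 0.898 CPM in the other tumor libraries. Xist was at 45.1, 3.01 and 27.0 CPM in naive replicates 1, 2 and 3, so naive replicate 3 had both, and whether it holds cells of animals of both sexes was not tested. Naive and tumor libraries of the same number may come from different animals, since Y-linked expression differed over 10-fold at all 3 shared numbers. An exchange of naive replicates 1 and 2 alone is argued against by the 204.8 CPM of naive replicate 3, which it would not touch. For naive replicates 1 and 2 themselves it stays open, because the lowest crossed autosomal correlation, -0.122, lay within the spread of naive and tumor pairs (SD 0.0921) of the limit set for it, a comparison with the SD that was decided after the value was seen.

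Ighm, an immunoglobulin heavy chain gene, was at 1191 to 1235 CPM in naive libraries. B cells in the sorted naive material are argued against, because the higher of Cd79a and Cd79b, abundant B cell transcripts, reached 2.26% of the Ighm level. Igkc, the light chain gene that B cells express in quantity, was at 0.289 to 3.66 CPM. No biological explanation was tested.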
